A study of Rattus norvegicus with 4 samples.

How the data were processed

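Total RNA from rat hearts was labelled with the dye Hy3 and hybridized to miRCURY LNA arrays, whose probes are made with locked nucleic acids, per the labels. The labels give 1 µg of RNA at day 2 and 500 ng at day 14. Groups were taken from the sample titles, because the treatment text is the same on all samples and describes the sham operation at day 2. Each of the 4 groups (sham and MI at day 2 and day 14) had 1 array of RNA pooled from 3 rats.

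The deposited scanner files hold the intensity of each spot and of its local background, quantified with Mapix 4.5.0 at 5 µm pixels, per the file headers. The headers name array version 11.0 with miRBase 12.0 names at day 2 and generation 6 with miRBase 16.0 names at day 14. The authors also deposited the percent of saturated pixels of each spot, which was not used in the calculations. The header of the day 2 sham scan names an image with the prefix of mouse, although its labels name rat; those of the other 3 arrays carry the prefix of rat. The 532 nm channel holds Hy3, and no dyed sample is named for the 635 nm channel. The deposited value table holds log2 values whose processing is not given in the sources used here.

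The value table was set against the scanner values of the same array. Spearman correlations over detected rat probes were between 0.991 and 1.00, and the slopes were 1.25 and 1.36 at day 2 and 1.17 and 1.22 at day 14, so the table is on a wider log2 scale. Column medians were 6.36 for both day 2 arrays and 4.70 for both day 14 arrays. The lowest values, 0.72, 0, 0 and 0.08, are shared by 110, 38, 63 and 89 rat probes, which have no order among themselves. The background correction and the centring behind the table stay unknown. The direction is not in doubt, since each column is one array. The table was used as an alternative.

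Median foreground was corrected for median local background with the normexp method of limma 3.58.1 in R 4.3.3, with an offset of 50, fitted on all spots. The 2 arrays of a day were quantile normalized over spots other than controls, and log2 values were averaged over the 4 spots of a probe. No spot carried a bad flag, so none was left out. A spot was detected when its foreground exceeded the background by over 2 background SDs, and a probe when at least 50% of its spots were. Rat probes detected on at least 1 array were counted, under the names on the array. A miRNA was called when MI and sham differed at least 2-fold. For a probe detected on 1 array the fold is a bound, the bright mean against the higher of the dim probe's mean and the lowest mean among detected probes of the dim array. A bound under 1-fold was set to 0 on the log2 scale. A probe with at least 50% of spots at the limit of 65535 was saturated, which gives a bound if it was the brighter array and otherwise no fold. With 1 array per group no test was possible.

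The miRNAs named are, for each day, the 10 highest and 10 lowest among those detected on both arrays, up to 3 per direction among those detected on 1, miR-31, and members of the lists. This rule, the 16 lists, the 5 lists for other tissues and the alternatives were fixed before the data were examined, except those said to be chosen later. miRNAs outside the rule that moved past 2-fold over 3 spot sets were named after their values were seen. miR-155 and miR-486 were not analysed here, nor were miR-208b and miR-665 at day 2. A list with at least 3 measured members was given the percentile of its median among 10000 random lists of the same size, drawn within 5 bins of mean intensity, as a description of these arrays.

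Signal over background limits the precision. The median local background was 322 intensity units on the day 2 sham array and 131 on the day 2 MI array, against 94 and 100 at day 14, and on the day 2 sham array it exceeded the median foreground of 301. The median spot SD of detected rat probes was 0.64 on the day 2 sham array, 0.15 on the day 2 MI array, and 0.13 and 0.08 on the day 14 sham and MI arrays. At day 2, 16 and 11 rat probes were saturated in sham and MI, and at day 14 none were. No correction was made for probes of near-identical miRNAs, which may share signal.

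The calculation was tested on simulated pairs of arrays with 200 changed probes each. For day 2, over 1737 probes, 19 of 20 rat probes simulated at 4-fold passed the rule, as did 18 of 20 at 2.46-fold, 0 of 20 at 1.5-fold and 0 of 139 unchanged. For day 14, over 2345 probes, the numbers were 20 of 20, 14 of 20, 1 of 20 and 0 of 154. The simulation held no dim spot set. Both simulated arrays took their levels and spot spread from the MI array, whose median spot SD at day 2 was 0.15 against 0.64 in sham. As many changes were simulated upward as downward, without a difference in scaling between the arrays. The 0 of 139 and 0 of 154 are therefore no rate of false calls for the real arrays. Simulated 4-fold changes came back at a median log2 of 1.86 at day 2 and 1.75 at day 14, below the simulated size, and 2.46-fold changes at 1.29 and 1.07, the latter below it. For the list percentile, 18 of 20 lists simulated with a shift and 0 of 20 without passed the upper tail. For neighbouring hairpins, 20 of 20 simulations with like neighbours and 2 of 20 without passed.

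Alternatives were no background correction, normexp with an offset of 10, subtraction with a floor of 16, centring on miRNAs detected on both arrays, cyclic loess, no normalization, quantile normalization over all 4 arrays, mean of pixels, detection at 1 background SD, detection on both arrays, no filter, the median of spots, probes of all species, the value table, and thresholds of 1.5-fold and 3-fold. Chosen after seeing the data were leaving out the fourth spot set at day 2, centring on the median over all spots of detected spike-in controls, and a shift by the median over spike-in probes of their mean difference. The array medians over spike-in spots differed by 0.0029 at day 2 and the probes by -0.30, so the former is close to no normalization there; at day 14 these values were 0.11 and 0.12. Neighbouring miRNA genes were taken from RefSeq genes of the assembly GRCr8, in which 639 of 677 rat probes of day 14 matched 1 hairpin by name; the files name no genome build, and no positions are given. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.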

Results

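The arrays measured microRNAs (miRNAs), short RNAs that repress target messenger RNAs, in heart tissue of male Wistar rats after myocardial infarction (MI) or a sham operation. MI was made by tying off a coronary artery, and the sham rats had their chest and pericardium opened. Hearts were taken at day 2 or day 14, and the RNA of 3 rats of a group was pooled before labelling. There were 4 arrays, 1 for each of the 4 groups, so no difference below has a check across replicates and no test was run. The errors given are standard errors of the difference over the 4 replicate spots of a probe and leave out the variation between rats and between arrays.

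The day 2 arrays held 348 rat miRNA probes, of which 166 were detected in the sham pool and 199 in the MI pool. The day 14 arrays, of a later generation and with less RNA, held 677 rat probes, of which 173 were detected in sham and 214 in MI. The design text gives 345 and 656 miRNAs as profiled at these days. Each array is a slide of its own, so slide and group cannot be told apart. The days differ in array generation and in RNA amount, and MI was therefore compared with sham within a day.

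The first comparison asked which miRNAs differed in the heart 2 days after infarction. miRNAs of blood leukocytes stood higher in the MI pool, 2 of the 4 measured being past 2-fold and all 4 above 0. miR-223, abundant in neutrophils and other myeloid cells, was 3.97-fold higher (log2 difference 1.99, SE 0.12). miR-142-3p, found in most blood cell lineages, was 3.33-fold higher (1.74, SE 0.88). Without a dim spot set of the sham array, described below, it was 1.18 higher. With the median of the spots it was 0.89 higher, under 2-fold. miR-21, which is induced in injured tissue, was at least 2.71-fold higher, a bound because its MI spots were saturated. In the authors' value table this bound was 1.12 on the log2 scale. miR-31, the miRNA in the series title, was detected in the MI pool only. With quantile normalization within the day it was at least 2.32-fold higher there (log2 1.21, SE 0.05). This bound holds for that scaling only: under 7 others it ran from 0.31 to 2.40 on the log2 scale and was past 2-fold in 2. At the other end, miR-336 was 2.78-fold lower in the MI pool (-1.47, SE 0.12).

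By the 2-fold rule, 8 rat miRNAs were higher and 2 were lower in the MI pool at day 2, and 177 of the 187 with a fold lay within 2-fold. The 8 higher ones were miR-223, miR-142-3p, miR-21, miR-193, miR-222, miR-10a-5p, miR-15b and miR-31, and the 2 lower ones were miR-336 and miR-138*. For 14 further detected probes saturation allowed no fold, among them those of miR-1, miR-133a and miR-208, which are made in heart muscle. The spots of the MI and sham arrays did not overlap for 8 of the 10 miRNAs past the rule.

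**Figure D1:**
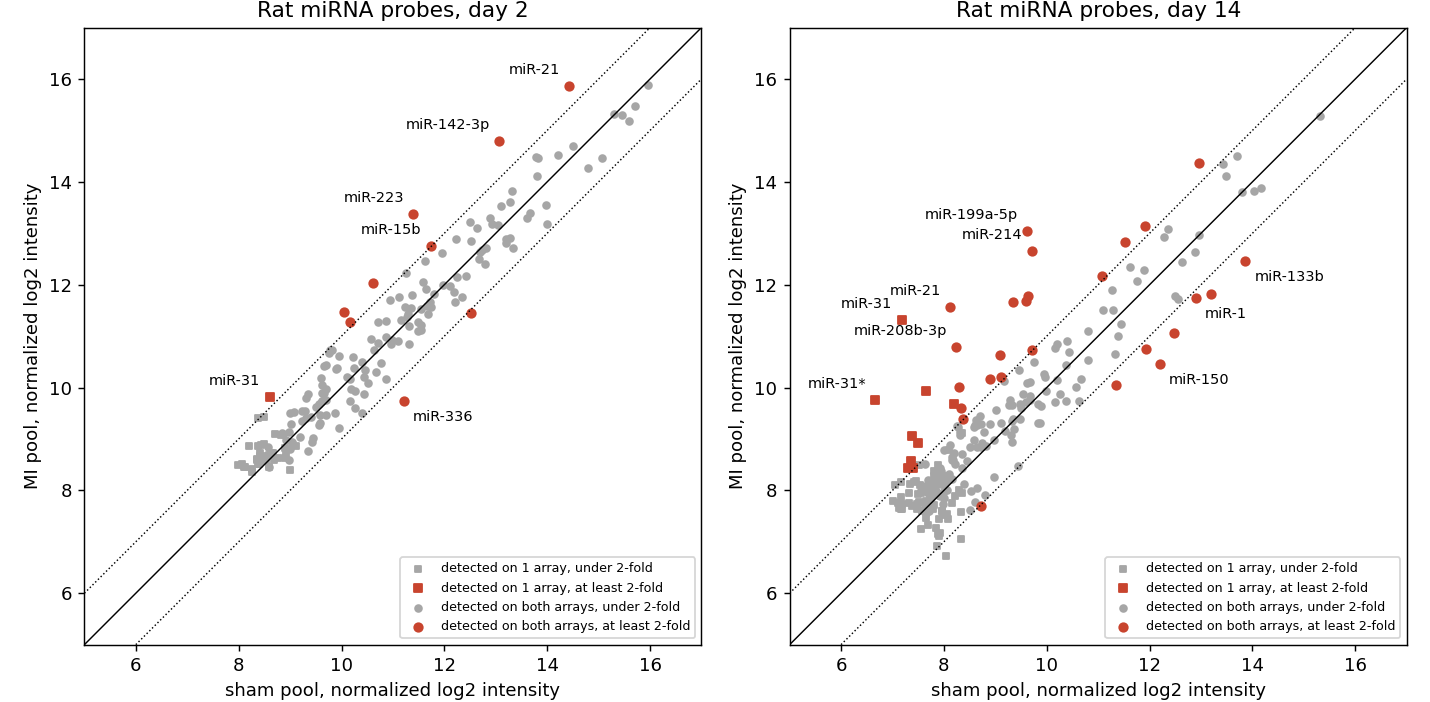
Normalized log2 intensity of rat miRNA probes in the MI pool (vertical axis) against the sham pool (horizontal axis) at day 2 (left) and day 14 (right), 1 array per group. Each point is the mean over a probe's 4 spots, squares are probes detected on 1 array, red marks probes at least 2-fold apart (by the bound for squares), the solid line is equality and the dotted lines are 2-fold; 8 points are red above the line at day 2 and 27 at day 14.

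The fourth of the 4 spot sets of the day 2 sham array was dim, with a median deviation of -0.71 log2 from the probe medians, and its local background was 542 intensity units against 278 to 344 in the other sets. Over the other 3 sets, a choice made after seeing the data, 7 miRNAs were higher and 2 lower, and 6 of the 8 higher miRNAs were shared. miR-10a-5p moved from 1.10 to 0.48 and miR-15b from 1.02 to 0.35 on the log2 scale, while miR-142-5p was added. miR-138* moved from -1.08 to -0.71 and miR-347 was added among the lower ones. With the median of the 4 spots, miR-142-3p was at 0.89 and miR-193 at 0.79, both under 2-fold. The values over 3 sets were 2.22 for miR-223 (SE 0.16), 1.18 for miR-142-3p (SE 0.06), 1.17 for miR-222 (SE 0.12), 1.02 for miR-193 (SE 0.09) and -1.29 for miR-336 (SE 0.15), with bounds of 1.65 for miR-21, whose MI spots were saturated, and 1.27 for miR-31, not detected in sham.

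**Figure D2:**
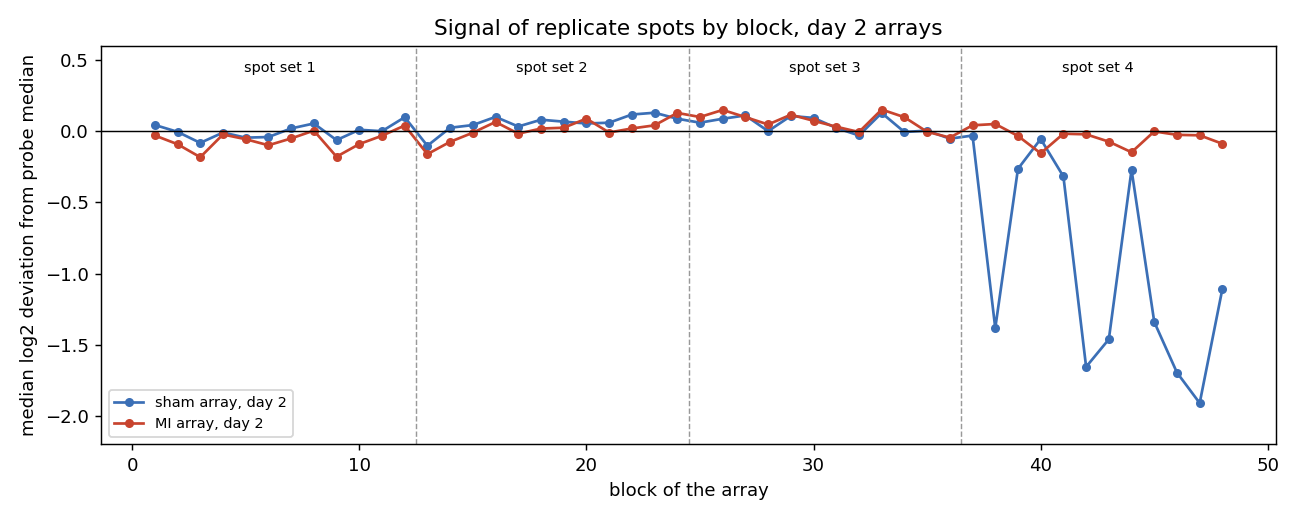
Median log2 deviation of replicate spots from their probe's median (vertical axis) in each block of the day 2 arrays (horizontal axis), for the sham array (blue) and the MI array (red), over probes detected on both. Dashed lines part the 4 spot sets; the sham array drops in the fourth set, whose median deviation is -0.71, and the MI array does not.

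Other miRNAs at the ends of the day 2 range stayed under 2-fold. miR-150, miR-338 and miR-674-5p were 0.97, 0.96 and 0.92 higher in the MI pool on the log2 scale with spot SEs of 0.77, 0.76 and 0.81, and 0.35, 0.36 and 0.42 higher over 3 spot sets. At the other end lay miR-99b* (-0.90), miR-207 (-0.82), miR-347 (-0.74), miR-291a-3p (-0.70), miR-125b-3p (-0.66), miR-206 (-0.61), miR-30e (-0.61) and miR-760-5p (-0.59). Among probes detected in MI only, miR-147 and miR-466b were at least 1.91-fold and 1.90-fold higher, but their differences were as low as 0.08 and 0.02 on the log2 scale in single alternatives. Among those detected in sham only, miR-181c and miR-376b-3p were at least 1.53-fold and 1.16-fold lower.

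The median of the 4 measured leukocyte miRNAs at day 2 was 1.35, at percentile 99.96 of 10000 random lists matched on intensity, and 1.12 over 3 spot sets (percentile 99.955). In this list miR-142-3p and miR-142-5p are arms of the same hairpin, which the random lists do not take into account. The inflammation-induced miRNAs had a median of 0.68 over 5 measured members, at percentile 99.5, and of 0.53 over 3 sets (percentile 99.9), with 1 member, miR-21, past 2-fold. This median was 0.055 without normalization and 0.35 when the arrays were shifted by their spike-in controls. miR-146a was 0.68 higher (SE 0.83) and 0.11 higher over 3 sets. All 7 measured let-7 miRNAs were below 0, from -0.52 to -0.18, with a median of -0.38 at percentile 3.25 and of -0.30 at percentile 7.44 over 3 sets, although let-7a was at 0.11 with centred arrays. These probes differ by few bases and may share signal, so single members are uncertain.

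Few heart muscle miRNAs had a value at day 2, because 3 of the 5 on the array were saturated. miR-133b was 0.33 higher (SE 0.60) and miR-499 was 0.51 higher (SE 0.97), and both were below 0 over 3 spot sets, at -0.11 and -0.29. The fibroblast and smooth muscle miRNAs had a median of -0.02 (percentile 40.4), and of -0.13 (percentile 45.5) over 3 sets, with none of 4 past 2-fold, and turned above 0 with centred arrays and with cyclic loess. The miR-15/16 family had a median of 0.65 (percentile 95.8), which was 0.05 (percentile 89.3) over 3 sets and below 0 with the median of spots. The miR-17-92 cluster and paralogues had a median of 0.14 (percentile 68.9) over 7 members, and of 0.11 (percentile 92.9) over 3 sets. The median was below 0 without normalization, with the median of spots, with quantile normalization over the 4 arrays and with arrays centred on spike-in spots. The miR-34 family had a median of 0.40 (percentile 94.2), which was 0.06 (percentile 85.8) over 3 sets, and 2 of its 3 values are bounds. The miR-23/24/27 clusters had a median of -0.06 (percentile 35.9), above 0 with centred arrays, with cyclic loess and over 3 sets (0.003, percentile 82.5). The 9 detected of the 34 Dlk1-Dio3 miRNAs had a median of -0.15 (percentile 1.54), which was -0.03 (percentile 49.5) over 3 sets and above 0 with cyclic loess. With fewer than 3 measured members, the miR-30 and miR-29 families had medians of -0.18 and 0.45. Endothelial miR-126* was at 0.11 and the erythroid median at 0.30, and both were below 0 over 3 sets (-0.46 and -0.05). The hypoxia miRNA miR-210 was not detected on either array.

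Day 2 calls depended on how the arrays were scaled. Without normalization between the arrays the median of the miRNAs detected on both moved from 0.07 to -0.45, and the calls were 4 higher and 23 lower. With the arrays shifted by the median difference of 8 spike-in control probes, which was -0.30 with probes between -0.94 and 0.07, the median was -0.16 and the calls were 5 higher and 10 lower; this scaling was chosen after seeing the data. Of the 8 higher miRNAs, miR-223, miR-142-3p, miR-21 and miR-193 stayed past 2-fold under both scalings. The bound of miR-31 then lay at 0.31 and 0.61, and at 0.81 with centred arrays and 0.83 with quantile normalization over the 4 arrays, all under 2-fold. Higher and lower miRNAs numbered 9 and 5 with centred arrays, 12 and 1 with cyclic loess, 4 and 2 with quantile normalization over the 4 arrays, and 25 and 19 in the authors' value table. Quantile normalization over the 4 arrays held 279 of the 348 rat probes. The value table is on a wider log2 scale, with slopes of 1.25 and 1.36, so the 2-fold cutoff is looser there.

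The second comparison asked which miRNAs differed 14 days after infarction, when a scar has formed. Of the fibroblast and smooth muscle miRNAs 3 of 5 were at least 2-fold higher in the MI pool, and of the heart muscle miRNAs 4 of 6 were at least 2-fold lower. Of these 4 heart muscle miRNAs, 0 stayed 2-fold lower without normalization or with either scaling by spike-in controls. miR-31 was detected in the MI pool only and was at least 16.9-fold higher there in the main processing (log2 4.08, SE 0.23). Over the alternatives this bound ran from 3.46 to 5.93 on the log2 scale. miR-21 was 10.9-fold higher (3.45, SE 0.09), miR-199a-5p 10.8-fold (3.43, SE 0.06) and miR-214 7.68-fold (2.94, SE 0.06). miR-133a and miR-133b, which are made in muscle, were 2.68-fold and 2.65-fold lower (-1.42, SE 0.06, and -1.41, SE 0.04).

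By the 2-fold rule, 27 rat miRNAs were higher and 8 were lower in the MI pool at day 14, and 195 of the 230 detected lay within 2-fold. For 9 of the 27 higher ones the value is a bound, since they were not detected in sham. Spots of the arrays did not overlap for 34 of the 35 miRNAs past the rule, let-7c being the exception with a spot SE of 0.99 and a value of -0.24 with the median of spots. The other highest miRNAs detected on both arrays were miR-208b-3p (2.55), miR-140* (2.32), miR-193 (2.14), miR-199a-3p (2.10), miR-223 (1.72), miR-152 (1.55) and miR-125b-5p (1.41). In MI only, miR-31*, the other arm of the miR-31 hairpin, was at least 5.76-fold higher and miR-222 at least 4.87-fold.

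The lowest value was that of miR-150, a miRNA of mature lymphocytes, at -1.74 (SE 0.13). It was followed by miR-133a, miR-133b, miR-208 (-1.37), miR-325-3p (-1.29), let-7c (-1.17), miR-1 (-1.16), miR-208* (-1.03), miR-129-1*/miR-129-2* (-0.98) and miR-103-1* (-0.91). In sham only, miR-191*, miR-292-3p and miR-129-2* were at least 1.94-fold, 1.70-fold and 1.58-fold lower, with spot SEs of 0.73, 0.97 and 0.73.

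**Figure D3:**
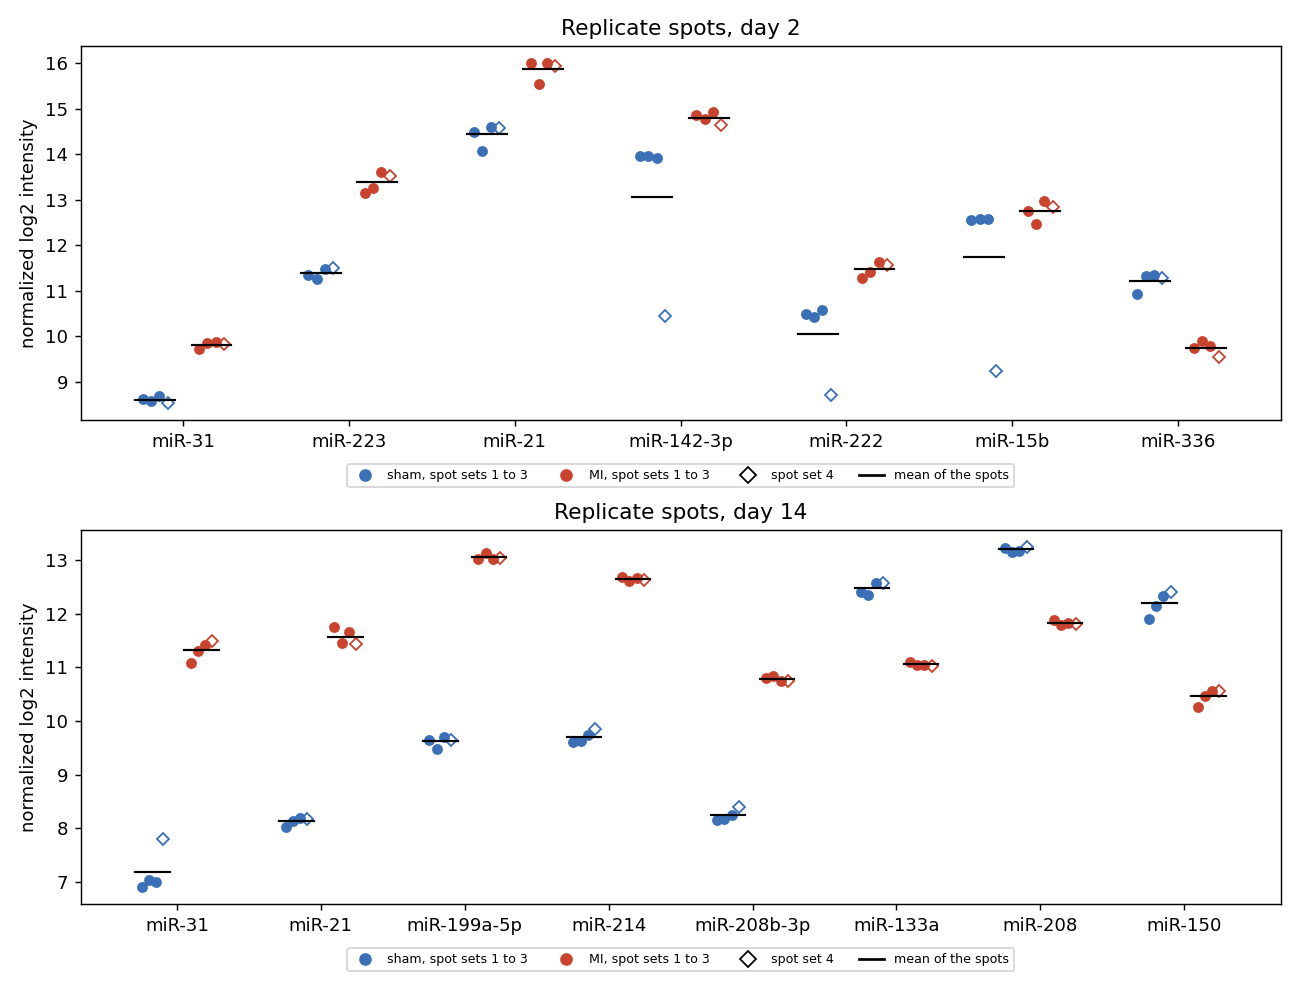
Normalized log2 intensity (vertical axis) of each of the 4 replicate spots of chosen miRNAs (horizontal axis) at day 2 (top) and day 14 (bottom), sham in blue and MI in red, with a bar at the mean of the spots and open diamonds for the fourth set. The sham diamonds of miR-142-3p, miR-222 and miR-15b fall far below their other spots at day 2, and miR-31 at day 14 stands at 7.18 in sham and 11.32 in MI.

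Of the 6 heart muscle miRNAs at day 14, 4 were at least 2-fold lower in the MI pool, 1 was higher and 1, miR-499, was at -0.66. Their median was -1.26, at percentile 0.045. All 4 stayed 2-fold lower with cyclic loess and in the authors' value table, and 3 with centred arrays. Without normalization, centred on spike-in spots and shifted by the difference of spike-in probes, 0 of the 4 did, and the 5 members other than miR-208b lay between -0.87 and -0.16, between -0.98 and -0.27 and between -0.99 and -0.28. The higher one was miR-208b-3p, encoded in the gene of a slow myosin heavy chain, at 5.84-fold, while miR-208, encoded in the gene of another cardiac myosin, was 2.59-fold lower. miR-133a and miR-133b, and miR-1 and miR-206, are nearly identical in sequence and may share signal. miR-206, of skeletal muscle, was at -0.70.

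The fibroblast and smooth muscle miRNAs had a median of 2.10 at day 14 (percentile 99.5), with 3 of 5 members at least 2-fold higher. Those were miR-199a-5p, miR-214 and miR-199a-3p, whereas miR-143 was at 0.81 and miR-145, of smooth muscle, at -0.15, which turned above 0 without normalization and with either scaling by spike-in controls. Endothelial miR-126 and miR-126* were at -0.29 and -0.39, and erythroid miR-451 and miR-144 at 0.01 and 0.21. miR-126 turned to 0.05 without normalization, and miR-451 and miR-144 turned below 0 in 4 and 2 alternatives. Of 4 measured leukocyte miRNAs, miR-223, miR-142-3p and miR-142-5p were past 2-fold higher (1.72, 1.23 and at least 1.48) and miR-150 was lower. Their median was 1.36, at percentile 97.6, with miR-142-3p and miR-142-5p from the same hairpin.

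All 3 members of the miR-34 family, induced by p53, were at least 2-fold higher at day 14, with a median of 1.26 (percentile 98.9); the values of miR-34b and miR-34c are bounds, and 2 of the 3 were past 2-fold with centred arrays, cyclic loess, the mean of pixels, either scaling by spike-in controls or the authors' value table. In the miR-15/16 family 3 of 5 were, led by miR-195 (1.31) and with miR-497 as a bound, with a median of 1.11 (percentile 98.4), and 1 of 5 was with centred arrays, cyclic loess or quantile normalization over the 4 arrays, and 2 of 5 were in the authors' value table. The 3 detected inflammation-induced miRNAs had a median of 0.96 (percentile 91.8), and the 5 of the miR-23/24/27 clusters had one of 0.71 (percentile 88.5), with miR-27b past 2-fold. The 7 detected members of the miR-17-92 cluster and paralogues lay between 0.34 and 0.87 (median 0.63, percentile 90.3). The let-7 median was 0.14 (percentile 33.5) and turned to -0.29 in the authors' value table and to -0.06 with cyclic loess. The miR-30 and miR-29 medians, -0.20 (percentile 19.7) and -0.37 (percentile 12.5), turned to 0.16 and 0.13 without normalization, to 0.05 and 0.02 with arrays centred on spike-in spots, and to 0.034 and 0.007 when shifted by the difference of spike-in probes. miR-210 was at 0.04, and the 5 detected members of the Dlk1-Dio3 cluster had a median of 0.00 (percentile 10.3). That median is the value of miR-543, detected in MI only with a difference of -0.31 (SE 0.71), which the rule for bounds set to 0. The values of miR-341 and miR-541 are bounds as well.

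**Figure D4:**
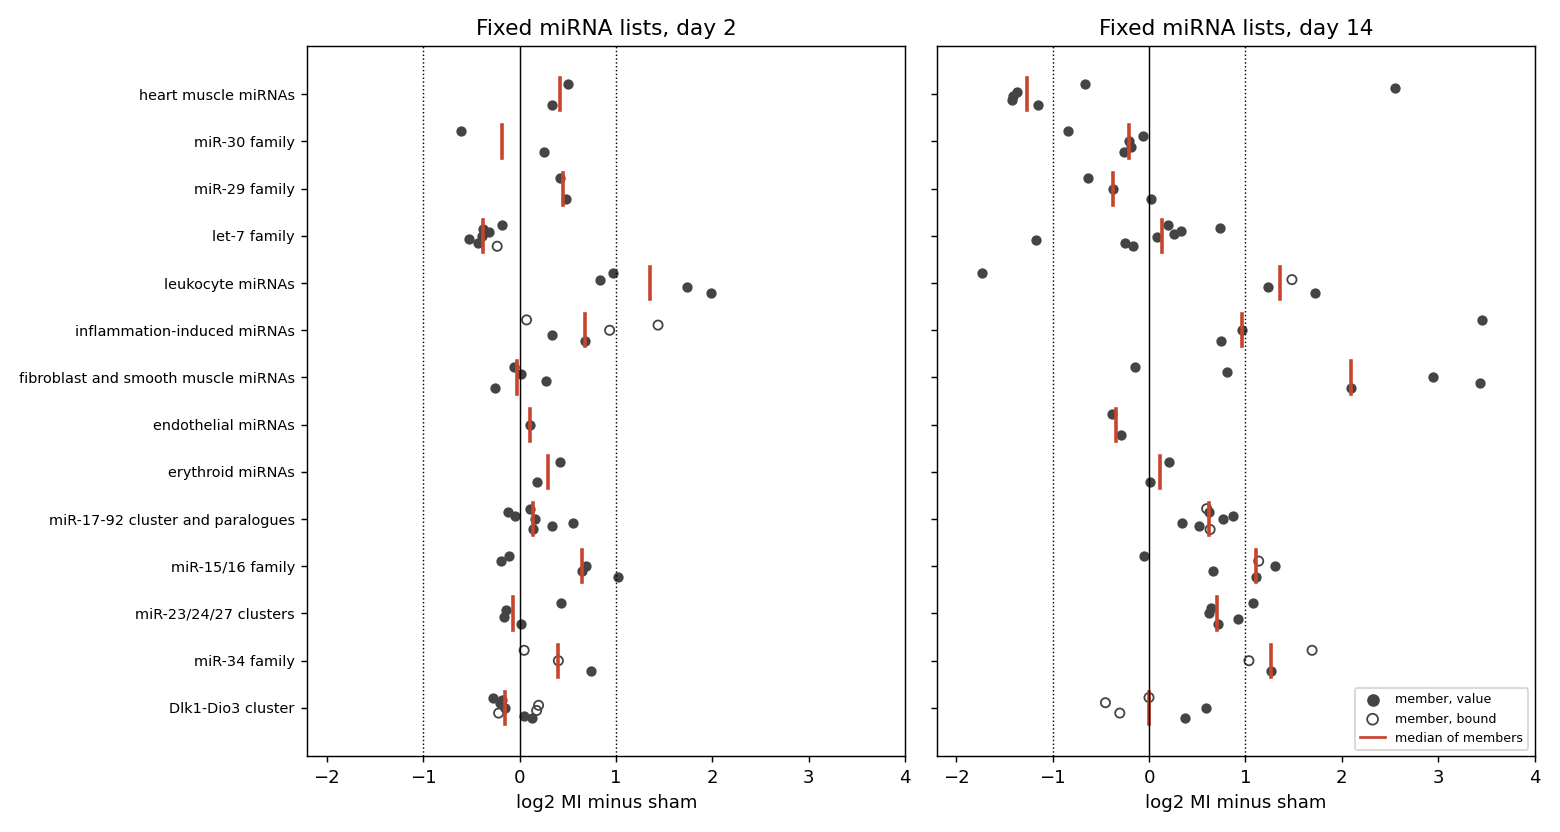
Log2 MI minus sham (horizontal axis) of the measured members of the miRNA lists that have more than 1 member (vertical axis), at day 2 (left) and day 14 (right). Filled points are values, open points are bounds, red bars are list medians and dotted lines mark 2-fold; the heart muscle median is -1.26 and the fibroblast and smooth muscle median 2.10 at day 14.

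Of the markers of other tissues, none was past 2-fold in the main processing. Some were in single alternatives. In the authors' value table miR-206 was at -1.51 at day 14 and miR-9 at -1.15 at day 2, and with local background subtracted miR-203 was at 1.08 at day 2. At day 2 skeletal muscle miR-206 was at -0.61, liver miR-122 had a bound of 0.09, neuronal miR-9 and miR-128 were at -0.41 and 0.27, epithelial miR-203 was at 0.14, and miR-128 and miR-203 were below 0 over 3 sets (-0.10 and -0.26), while pancreatic miR-375 had a bound of 0.00. At day 14 miR-206 was at -0.70, miR-9 and miR-128 had bounds of 0.04 and -0.19, and epithelial miR-205 had a bound of 0.41. miR-122 and the pancreatic miRNAs were not detected at day 14.

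The balance of calls at day 14 moved with the scaling. The median of the miRNAs detected on both arrays was 0.24, and it was -0.01 with arrays centred on these miRNAs, where 21 were higher and 23 lower, and 0.46 without normalization, where 42 were higher and 1, miR-150, lower. Higher and lower miRNAs numbered 21 and 13 with cyclic loess, 36 and 3 with arrays centred on spike-in spots, which kept miR-150 and miR-208* of the 8 lower ones, 36 and 4 when shifted by the difference of spike-in probes, and 35 and 27 in the values processed by the authors. Those values are on a wider log2 scale, with slopes of 1.17 and 1.22 against the scanner values.

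The last comparison set the days side by side. Across the 73 rat miRNAs detected on all 4 arrays, paired by probe, the MI differences at day 2 and day 14 correlated with Pearson's r of 0.29 (bootstrap 95% interval 0.07 to 0.51) and Spearman's rho of 0.24. These are correlations across miRNAs, which are not independent replicates. Without miR-223 and miR-142-3p, the miRNAs farthest from the day 2 median, r was 0.21. Signs were the same for 42 of the 73, and for 33 of 75 when the fourth spot set was left out. At least 2-fold higher at both days were 4 of the 73, and paired by name 5 of 94, while over the first 3 spot sets it was 3 of 75. miR-31 and miR-222 also passed the rule at both days, but they are left out of these counts because they were not detected on all 4 arrays.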

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

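All tests in this part were chosen after part of the values they measure had been seen. MI differences had opposite signs at day 2 and day 14 for 31 of the 73 miRNAs paired by probe and for 39 of the 94 paired by name, and none of these differences between days was tested. Among the miRNAs that were picked by size or for detection on 1 array, these were miR-133b, miR-138*, miR-140*, miR-150, miR-152, miR-199a-3p, miR-291a-3p and miR-325-3p. Members of the lists are left out here unless so picked, such as miR-499 with 0.51 and -0.66. From day 2 to day 14 the log2 difference moved by -2.70 for miR-150, by -1.74 for miR-133b and by -1.56 for miR-325-3p. It moved by 2.40 for miR-140*, 2.35 for miR-199a-3p, 1.81 for miR-152, 1.43 for miR-138* and 0.91 for miR-291a-3p. At day 2 miR-140* was at -0.09 (SE 0.32), miR-199a-3p at -0.25 (SE 0.22) and miR-152 at -0.26 (SE 0.26), so these signs are uncertain. miR-291a-3p was at 0.21 at day 14, where the median of the miRNAs detected on both arrays was 0.24. miR-150 and miR-133b were paired by name only and had another probe at each day, so probe and time cannot be told apart for them. Over the first 3 spot sets miR-133b and miR-325-3p were at -0.11 and -0.15 at day 2, so their sign was then the same at both days, while miR-150 stayed above 0 at 0.35.

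Outside the rat probes, several kinds of probe were detected in larger number on an MI array than on the sham array of the day. The same held for rat probes, with 199 against 166 at day 2 and 214 against 173 at day 14. Detection is set against the local background, whose median was 322 on the day 2 sham array and 131 on the day 2 MI array. Of 119 viral miRNA probes at day 2 and 202 at day 14, 26 and 30 were detected on the MI arrays, against 20 and 27 on the sham arrays. Human or mouse miRNA probes without a rat name gave 388 of 1270 on the day 2 MI array against 304 in sham. At day 14 they gave 266 of 1466 against 245. A negative control probe was detected on the day 2 MI array (1 of 7, against 0 in sham). In the second scanner channel, for which no dyed sample is named, 367 spots were detected on the day 14 MI array against 325 in sham, while at day 2 the order was the reverse, 567 against 622. The unnormalized signal of spike-in controls and of small RNA controls differed by -0.30 and -0.35 between MI and sham at day 2, and by 0.12 and 0.39 at day 14.

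The first pattern is the set of 8 rat miRNAs at least 2-fold higher in MI at day 2, set against the fourth, dim spot set of the sham array and against the scaling. Over the other 3 sets, which also took part in picking the 8, 4 stayed past 2-fold by more than 2 spot SEs, namely miR-223 at 2.22 (SE 0.16), miR-142-3p at 1.18 (SE 0.06), and miR-21 and miR-31 with bounds of 1.65 and 1.27. This argues against the dim set as the whole cause, although miR-222 and miR-193 passed by less and miR-10a-5p and miR-15b fell under 2-fold. With the median of the 4 spots, 4 of the 8 stayed past 2-fold, namely miR-21, miR-222, miR-223 and miR-31. miR-142-3p was then at 0.89 and miR-193 at 0.79, so the place of miR-142-3p depends on how the dim set is handled. The scaling as the whole cause stays open. miR-223, miR-142-3p and miR-193 stayed past 2-fold under each of 7 other scalings, as did miR-21 in the 6 that hold it. By more than 2 spot SEs 1 of the 8 did so, miR-223 with 1.68 or more, and miR-31 went down to 0.31. The spot SEs include the dim set, and were 0.88 for miR-142-3p and 0.68 for miR-193 in the main processing. For such miRNAs the count beyond 2 SEs therefore cannot judge the scaling. The infarction itself also stays open and was not tested.

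The second pattern is the mouse prefix in the header of the day 2 sham scan. If mouse RNA had been on that array, rat-only probes could stand higher in MI relative to mouse-only probes. The difference of medians was -0.06 (bootstrap 95% interval -0.63 to 0.14, 14 rat-only and 84 mouse-only probes), and -0.10 over 3 spot sets. Probe names do not show that the other species lacks the sequence, so rat and mouse RNA cannot be told apart by this value. No biological explanation was tested.

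The third pattern is the lower level of most heart muscle miRNAs with higher fibroblast miRNAs in MI at day 14. The gap between the fibroblast and smooth muscle median and the endothelial median was 2.44. It argues against a lower share of heart muscle RNA alone as the whole cause, which would leave these medians alike. The gap rests on few genes. miR-199a-5p and miR-199a-3p are arms of the same hairpin with miR-214 as a neighbour, and miR-126 and miR-126* are arms of another. In the same list miR-143 and miR-145 were at 0.81 and -0.15. Changes of several cell types together stay open and were not tested. Quantile normalization as the cause of the direction is argued against by the heart muscle median without miR-208b, which was -1.37 and became -0.95 with arrays centred on spike-in spots, with the 5 members between -0.98 and -0.27. The 2-fold calls do not need quantile normalization, since all 4 stayed with cyclic loess and in the authors' value table and 3 with centred arrays, but setting the 2 arrays to a common level as their cause stays open, since 0 of the 4 stayed with arrays centred on spike-in spots, where the median of all miRNAs detected on both arrays moved from 0.24 to 0.35. Cross-hybridization of single probes stays open as well, because both arms went the same way in 88.9% of the 9 hairpins with an arm past 2-fold (exact 95% interval 51.8 to 99.7, miR-34b being the exception), as do the hypotheses of a change in the fibroblasts and of the infarction, which were not tested.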

How the results depend on the processing

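Leaving out the fourth spot set and the 2 scalings by spike-in controls were alternatives chosen after seeing the data. Over all alternatives, 321 values stayed within the spread between spots, or within 1.5 times the count, and 118 moved by more, while 0 called values reversed. The day 2 spread includes the dim spot set, so it is a wide limit. The 25 miRNAs of day 2 and 26 of day 14 that were named by size or for detection on 1 array, miR-31 included, changed sign in no alternative run for them. Most were picked for large differences in these same data, so a kept sign follows in part from the choice. Of the list members with a value, 34 of 64 at day 2 and 24 of 69 at day 14 changed sign in at least 1. The day 2 medians of leukocyte miRNAs (0.83 to 1.79) and let-7 (-0.68 to -0.20), the day 14 heart muscle median (-1.32 to -0.67) and the correlation between days (0.24 to 0.34) kept their sign throughout. At day 14, the bound of miR-31 stayed between 3.46 and 5.93. The median difference of miRNAs detected on both arrays shifted at day 2 from 0.07 to -0.45 without normalization or centred on spike-in spots, whose array medians differed by 0.0029, to -0.16 shifted by the spike-in difference per probe, 0.19 with cyclic loess, -0.17 in the value table, -0.25 with the median of spots and -0.13 over 3 sets. At day 14 it shifted from 0.24 to 0.46 without normalization, 0.35 centred on spike-in spots, 0.34 shifted by the difference per probe, 0.38 with the mean of pixels, -0.01 with centred arrays, 0.09 with cyclic loess or quantile normalization over the 4 arrays, and -0.16 in the value table. Folds near 2 move with these shifts. The high background and spot spread of the day 2 sham array limit the precision there.

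The values that moved by more are given by alternative, with miRNAs at least 2-fold higher or lower as counts and lists by their median log2 difference. Those of miR-31 are bounds. With an offset of 10, day 2 had 13 higher and miR-31 at 1.32, and day 14 had miR-31 at 4.61. With local background subtracted, day 2 had 30 higher, 9 lower and miR-31 at 2.79, and day 14 had 59 higher, 18 lower, miR-31 at 5.93, leukocyte at 1.62, fibroblast and smooth muscle at 2.28, miR-17-92 at 1.00, miR-15/16 at 1.301 and miR-34 at 2.46. Without normalization between arrays, day 2 had 4 higher, 23 lower, miR-31 at 0.31 and inflammation-induced at 0.055, and day 14 had 42 higher, 1 lower, heart muscle at -0.67, miR-30 at 0.16, miR-29 at 0.13, let-7 at 0.47, leukocyte at 1.72, inflammation-induced at 1.32, fibroblast and smooth muscle at 2.63, miR-15/16 at 1.28, miR-23/24/27 at 1.299 and miR-34 at 1.49. With quantile normalization over the 4 arrays, day 2 had 4 higher and miR-31 at 0.83, and day 14 had miR-30 at -0.48, miR-29 at -0.74, inflammation-induced at 0.54, fibroblast and smooth muscle at 1.66, miR-15/16 at 0.86, miR-23/24/27 at 0.38 and miR-34 at 1.39. With the median of spots, day 2 had 4 higher and miR-31 at 1.00. In the authors' value table, day 2 had 25 higher, 19 lower and a miR-31 bound of 2.40. Day 14 had 27 lower, a miR-31 bound of 5.74, miR-30 at -0.60, miR-29 at -0.75, let-7 at -0.29 and inflammation-induced at 0.57. Fibroblast and smooth muscle was at 1.95 there, miR-15/16 at 0.76, miR-23/24/27 at 0.50 and miR-34 at 2.12. The differences of miR-31 in that table, before the rule for bounds, were 2.91 at day 2 and 6.94 at day 14. Centred on spike-in spots, day 2 had 4 higher, 23 lower, miR-31 at 0.31 and inflammation-induced at 0.052, and day 14 had 3 lower, heart muscle at -0.78, miR-30 at 0.048, miR-29 at 0.021, let-7 at 0.36, leukocyte at 1.61, inflammation-induced at 1.21, fibroblast and smooth muscle at 2.52, miR-23/24/27 at 1.19 and miR-34 at 1.38. Shifted by the spike-in difference per probe, day 2 had 5 higher, 10 lower and miR-31 at 0.61, and day 14 had 4 lower, heart muscle at -0.80, miR-30 at 0.034, miR-29 at 0.007, let-7 at 0.35, leukocyte at 1.60, inflammation-induced at 1.19, fibroblast and smooth muscle at 2.51 and miR-23/24/27 at 1.18. With probes of all species, day 2 had 15 higher and 8 lower, and day 14 had 28 lower. At 1.5-fold, day 2 had 26 higher and 11 lower, and day 14 had 63 higher and 23 lower. At 3-fold, day 2 had 2 higher and 0 lower, and day 14 had 12 higher and 1 lower. With centred arrays, day 2 had 5 lower and miR-31 at 0.81, and day 14 had 23 lower, miR-30 at -0.31, miR-17-92 at 0.28, miR-15/16 at 0.81, miR-23/24/27 at 0.83 and miR-34 at 1.02. With cyclic loess, day 2 had 1 lower, and day 14 had 13 lower, miR-30 at -0.46, let-7 at -0.055, leukocyte at 1.18, miR-17-92 at 0.44, miR-15/16 at 0.93 and miR-34 at 1.04. Without a filter, day 2 had 4 lower, and day 14 had inflammation-induced at 0.64. Without background correction, day 2 had miR-31 at 1.32, and day 14 had miR-31 at 3.57. With the mean of pixels, day 14 had miR-31 at 3.46, inflammation-induced at 1.16, fibroblast and smooth muscle at 2.24, miR-17-92 at 0.82 and miR-34 at 1.38. With detection on both arrays, day 14 had leukocyte at 1.23 and miR-15/16 at 0.88.

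The thresholds, the added species and the filters move counts by construction, and for the others the cause was not tested. Detection at 1 background SD moved none of the values by more than these limits. The limits cannot judge the values without the fourth spot set, since they include that set: the miR-15/16 median went from 0.65 to 0.05 and the miR-34 median from 0.40 to 0.056, and the set changed which miRNAs passed the rule. The joint normalization held 279 of 348 and 365 of 677 rat probes, and 344 of the 348 and 649 of the 677 matched the authors' values. Probes of all species were not run for the lists, whose members have rat names, and detection on both arrays gives the same correlation by construction. No paired analysis was possible because each pool was used on 1 array.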

Other observations

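The tests in this part were chosen after some of the values they measure had been seen. The miRNAs named here were chosen after their values were seen. At day 14 both arms of a hairpin had values other than 0 for 34 hairpins, of which 25 had arms of the same sign and 9 of opposite sign. In the main processing miR-31 and miR-31* were at least 4.08 and 2.53 higher on the log2 scale. miR-199a-5p and miR-199a-3p were 3.43 and 2.10 higher, and miR-542-3p and miR-542-5p 1.01 and 0.73. miR-208 and miR-208* were at -1.37 and -1.03, and miR-499 and miR-499* at -0.66 and -0.61. miR-21 and miR-21* were unequal, at 3.45 and 0.53. Arms of opposite sign were found for miR-34b and miR-34b* (a bound of 1.04, and -0.24), miR-191 and miR-191* (0.52, and a bound of -0.95), miR-26b and miR-26b* (0.29, and a bound of -0.51) and miR-331 and miR-331* (a bound of 0.49, and -0.26), among others.

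It was asked as a hypothesis whether miRNAs whose genes neighbour each other have like differences at day 14, which might come from shared transcripts. Among 50 pairs of neighbours within 10000 bases, over 174 miRNAs, the median absolute gap was 0.44 on the log2 scale. Random reassignment of the values gave a median gap of 0.63, and 3.08% of 10000 reassignments gave a gap as small; simulations without like neighbours passed in 2 of 20 cases. miR-199a-5p and miR-214 (3.43 and 2.94), miR-497 and miR-195 (1.14 and 1.31), and miR-133a and miR-1, with miR-3571 between them (-1.42, -1.16 and -0.51), are examples, the value of miR-497 being a bound. Other pairs went apart, such as miR-145 and miR-143 (-0.15 and 0.81) and miR-34c and miR-34b* (a bound of 1.69, and -0.24).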
